A study of Ovis aries with 10 samples.

How the data were processed

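Circular RNAs (circRNAs, transcripts closed by a junction between a downstream and an upstream splice site) were profiled in 10 samples of small-tailed Han sheep, 5 after sham surgery and 5 after ovariectomy. Their labels name longissimus dorsi, a back muscle, as the tissue. The groups and replicate numbers came from the sample titles and the design text. The labels also call the samples primary myoblasts and give a culture protocol with an estradiol series, but no sample carries an estradiol dose. Whether the RNA came from whole muscle or from cultured cells is therefore not settled by the labels. The labels do not state that each library came from a different animal, so p-values measure the spread between these samples.

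Libraries were made with a directional RNA kit, per the labels' protocols, and HISAT2 is the tool named in the submitters' processing notes. The circRNA caller, the genome build and the annotation are not given in the sources used here. For each circRNA the deposited table packs the whole-number counts of junction reads and of non-junction reads into comma-separated lists with the sample names. The non-junction reads are not defined in the sources used here and were taken as reads at the ends of a circRNA that do not cross its junction. The smallest listed count is 2 reads. A library without an entry for a circRNA is called not listed and was entered as 0 reads. The file holds 11297 circRNAs, of which 8721 are listed in the 10 libraries. Another 10 sample names in the lists belong to no sample of the series and were not used. The second deposited table gives, per the file headers, the authors' mean normalized read signal of each group, a log2 fold change of sham over ovariectomized, a p-value and an adjusted p-value. The authors' group means of signal equal the junction counts divided by median-of-ratios size factors, with a largest gap of 3.2e-07. Coordinates are those of the files, with starts counted from 1. Chromosome numbers were assigned to the files' sequences through the chromosome of the host genes in the ARS-UI_Ramb_v3.0 gene table, on which 10914 of 10916 circRNAs matched. Of the 8721 circRNAs, 8432 had a host gene ID found in that table.

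The comparison was planned with a count model for plain count columns. The deposited counts are packed in lists, and the main test was instead limma voom on the unpacked counts (limma 3.58.1, R 4.3.3, statmod 1.5.0), chosen before any fit was run. Library sizes were scaled by trimmed mean of M values, with 30% of log ratios and 5% of abundances trimmed at each end. A circRNA was tested when at least 5 libraries reached 10 reads scaled to the median library and its total was at least 15. This left 738 circRNAs, which hold 68.0% of junction reads. The fit used group as the only term, robust empirical Bayes variances and Benjamini-Hochberg adjustment with a threshold of 0.05. Values are normalized junction reads, junction reads divided by the scaled library size relative to the geometric mean. Differences in library measures and in circRNAs under the filter were tested with two-sided exact permutation tests over 252 relabellings, whose smallest possible p is 0.00794.

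Reads were also summed over the circRNAs of each host gene, and 753 of 3436 hosts passed the same filter. The 25 gene lists written before the data were examined cover estrogen targets, the MAPK pathway, muscle regulators, fiber types, growth, degradation, energy metabolism, other cell types, stress and the clock. Lists with at least 5 tested hosts were tested with limma's camera at a preset correlation of 0.01. The text names, by a rule fixed at the same time, circRNAs past the threshold with a known host. Where fewer than 3 passed in a direction, it names the 5 with the smallest p in that direction as not passing. It also names the study genes MAPK15, FAM171A1, ESR1, ESR2 and GPER1, and for each list the 2 tested hosts with the smallest p where none passed. Of these, 2 hosts are not reported here. The circRNA of the series title is not matched by ID or coordinates, so circRNAs of FAM171A1 are given as circRNAs of that host.

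The functions were tested on simulated counts drawn from the real means, spread and library sizes of this comparison, with 200 changed circRNAs. At 1.5-fold, 0.575% of the changed circRNAs that passed the filter were recovered among 719 tested. At 2-fold the share was 19.3% among 712 tested, and at 4-fold 92.4% among 726 tested. Among 20 simulated sets with no change, 0 gave a call. The median standard error of a log2 fold change in the real fit was 0.42. Alternatives covered other scalings, filters, variance models, a replicate block, host sums, a looser threshold and leaving out each library.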

Results

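Junction reads were counted in 5 libraries from sham-operated and 5 from ovariectomized sheep, to study the effect of estrogen on muscle of females. The sham libraries held 36971, 35731, 49887, 41557 and 46079 junction reads for replicates 1 to 5. The ovariectomized libraries held 41444, 40650, 39045, 46968 and 67061. Of the 8721 circRNAs, 7926 were exonic, 547 intronic and 248 intergenic, and exonic circRNAs took 94.3% of junction reads. A host gene was given for 8473 circRNAs, from 3436 genes. Only 806 circRNAs were listed in all 10 libraries, and 3270 (37.5%) were listed in a single library. The median spliced length was 291.0 bp.

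The numbers of circRNAs per host were highest for TTN, NEB, ABCC9 and DMD. TTN, which encodes the sarcomeric spring titin, gave 125 circRNAs with 12696 junction reads. NEB, which encodes the thin filament protein nebulin, gave 51 circRNAs. ABCC9, which encodes a subunit of potassium channels, gave 19, and DMD, which encodes dystrophin, gave 18. Of the 21 genes on the list of transcripts abundant in adult muscle fibers, 17 hosted a circRNA. None of the 35 cell proliferation genes did, and neither did any of the 13 blood genes or the 13 mitochondrially encoded genes. Among markers of other cell types, 8 of 18 endothelial, 4 of 16 smooth muscle and pericyte, 5 of 32 matrix and fibroblast, 4 of 26 adipocyte, 2 of 14 Schwann cell and 1 of 31 immune genes hosted a circRNA. These counts were not set against the length or exons of the genes, so they do not measure cell content. By total reads the leading hosts were SENP6, which encodes a SUMO protease, with 29990 reads, TTN, the ubiquitin ligase gene UBE3A with 12596, and ANO5, a gene of the anoctamin family, with 7278.

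**Figure D1:**
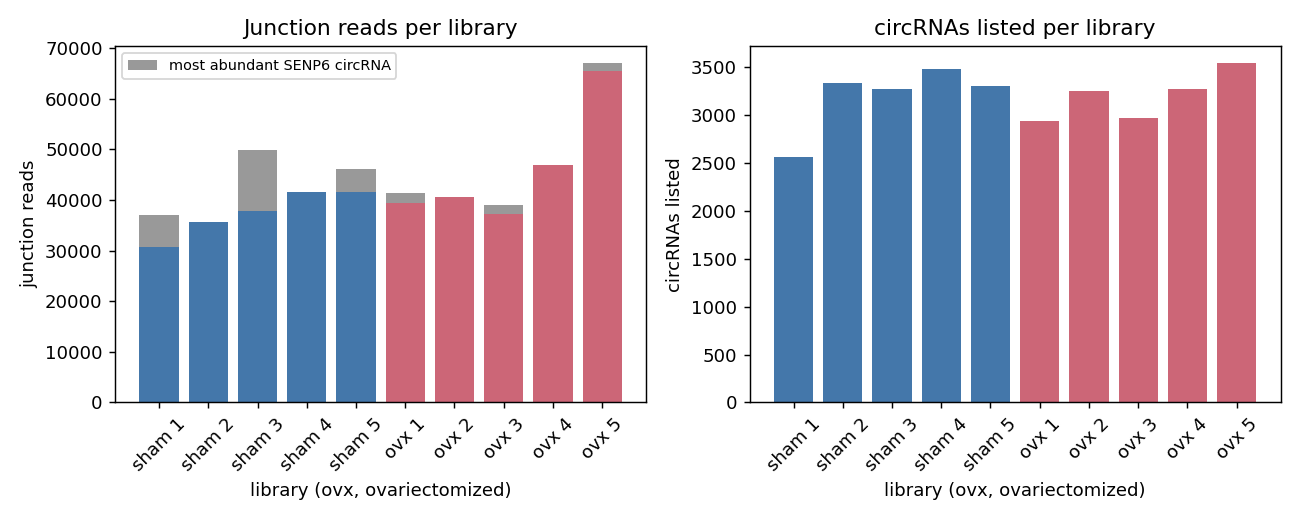
Junction reads (left) and number of circRNAs listed (right) in each of the 10 libraries, sham in blue and ovariectomized (ovx) in red, with the reads of the most abundant SENP6 circRNA in grey. Totals run from 35731 to 67061 reads, and the SENP6 circRNA takes up to 24.3% of a library.

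Library-level measures differed by less than the spread between replicates. Mean junction reads were 42045 ± 5992 (SD, n = 5) in sham and 47034 ± 11586 (SD, n = 5) in ovariectomized libraries, an exact permutation p of 0.50. The number of circRNAs listed was 3191 ± 362 (SD, n = 5) in sham and 3194 ± 249.7 (SD, n = 5) in ovariectomized libraries, with an exact p of 0.984. The 10 most abundant circRNAs took 19.9% ± 9.84 of sham reads and 14.0% ± 1.81 of ovariectomized reads, with an exact p of 0.254. Exonic circRNAs took 94.5% ± 1.03 and 94.1% ± 0.638 of reads, with an exact p of 0.50. Without the SENP6 circRNA named below, the difference in the share of the 10 most abundant turned from -5.93 to 1.01 percentage points and that in the exonic share from -0.399 to 0.0487. Over these 4 measures the smallest Benjamini-Hochberg adjusted exact p was 0.667.

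No circRNA differed between ovariectomized and sham libraries past the threshold in the limma voom fit. The smallest of the 738 adjusted p-values was 0.208. At an unadjusted p under 0.05 there were 42 circRNAs, against 36.9 expected by chance, 9 higher and 33 lower after ovariectomy. This split moved with the scaling, to 9 higher and 25 lower under median-of-ratios factors and 27 higher and 12 lower with library totals alone. It was 21 higher and 21 lower in limma trend on the authors' normalized values with a pseudocount of 1, and 24 higher and 11 lower without ovariectomized replicate 5. The median log2 fold change of all tested circRNAs moved from -0.04 to 0.14 with library totals alone. The limma fit called 4 circRNAs when those with 2 or more reads in at least 5 libraries were tested, and 30 of 8721 with no filter beyond 1 read. The 4 were those of LOC105605336, UBE3A, TANK and, named after its values were seen, novel_circ_0001213 of PCNT. Those of LOC105605336, LRP6 and TANK were among the 30. Of 100 drawn splits of the libraries into 5 and 5, 74 besides the real grouping also gave a call under the filter of at least 5 libraries. No count of splits is given for the setting with no filter. The authors' deposited table gives 118 of 8721 circRNAs a p under 0.05, with 47 higher and 71 lower after ovariectomy, and 1 an adjusted p under 0.05. Evenly spread p-values would give 436, but 3270 circRNAs were listed in a single library. With so few entries p-values are not evenly spread, so 436 is not what chance gives here. Of the 118, 37 are among the 738 circRNAs tested here.

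The circRNAs with the smallest p among those higher after ovariectomy were led by novel_circ_0017141, none of them past the threshold. It lies on X from 1937789 to 1945133 on the minus strand and spans exons of LOC105605336, annotated as a long noncoding RNA gene. It had 37.7 ± 13.9 normalized junction reads in sham and 96.9 ± 29.6 in ovariectomized libraries (SD, n = 5 each). Its log2 fold change was 1.35 ± 0.29 (SE), with a limma adjusted p of 0.208. That adjusted p was 7.57e-05 with no filter beyond 1 read and 0.00259 with at least 5 libraries at 2 or more reads, and it reached 0.717 without sham replicate 3. It was 0.0109 with the replicate number as a block. All 5 ovariectomized libraries, with 69 to 165 reads, lay above all 5 sham libraries, with 22 to 61. This LOC105605336 circRNA is the one with an adjusted p under 0.05 in the authors' deposited table, where that p is 0.0142. The UBE3A circRNA novel_circ_0013887 (chromosome 18, 1674006 to 1679847), the most abundant circRNA listed in all libraries, had 1018 ± 148.8 normalized reads in sham and 1376 ± 213 in ovariectomized libraries (SD, n = 5 each). Its log2 fold change was 0.44 ± 0.14 with a limma adjusted p of 0.781. That adjusted p was 1.23e-05 with at least 5 libraries at 2 or more reads and 0.256 with no filter beyond 1 read. Log2 fold changes were 0.99 ± 0.35 for novel_circ_0005017 of LRP6, the Wnt co-receptor gene (chromosome 3, 203315652 to 203323540), and 0.66 ± 0.26 for novel_circ_0013734 of KCTD10 (chromosome 17, 63863753 to 63865837). The VAPA circRNA novel_circ_0015941 (chromosome 23, 42427513 to 42431328) had a log2 fold change of 1.17 ± 0.49, and of 0.62 without sham replicate 5. All 3 had a limma adjusted p of 0.781.

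Among those lower after ovariectomy, none passed the threshold either. The smallest p was that of novel_circ_0009012 of REV3L, which encodes the catalytic subunit of DNA polymerase zeta (chromosome 8, 26257148 to 26322799). It had 39.2 ± 12.6 normalized reads in sham and 17.1 ± 1.47 in ovariectomized libraries (SD, n = 5 each), a log2 fold change of -1.14 ± 0.29 and a limma adjusted p of 0.407. Its normalized reads did not overlap between the groups, at 15.6 to 19.0 in ovariectomized and 28.6 to 55.1 in sham libraries. For novel_circ_0016529 of NDST2, a heparan sulfate sulfotransferase gene (chromosome 25, 28916675 to 28917298), normalized reads were 24.1 ± 2.36 in sham and 11.1 ± 5.38 in ovariectomized libraries (SD, n = 5 each), again without overlap. The TANK circRNA novel_circ_0002768 (chromosome 2, 148573567 to 148596062) was listed in 5 sham and 3 ovariectomized libraries. It had 25.6 ± 7.64 normalized reads in sham and 14.0 ± 13.5 in ovariectomized libraries (SD, n = 5 each), where replicates 1 and 5 had no entry. Its fitted log2 fold change was -3.42 ± 1.18, against -1.32 without ovariectomized replicate 5, -1.92 in limma trend with a pseudocount of 1 and -0.87 in the authors' deposited table. Log2 fold changes were -0.86 ± 0.31 for novel_circ_0007839 of TTC7B (chromosome 7, 100290110 to 100308505) and -0.97 ± 0.35 for novel_circ_0015927 of RAB12, a small GTPase gene (chromosome 23, 41585003 to 41593368). The limma adjusted p of the NDST2, TANK, TTC7B and RAB12 circRNAs was 0.781.

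**Figure D2:**
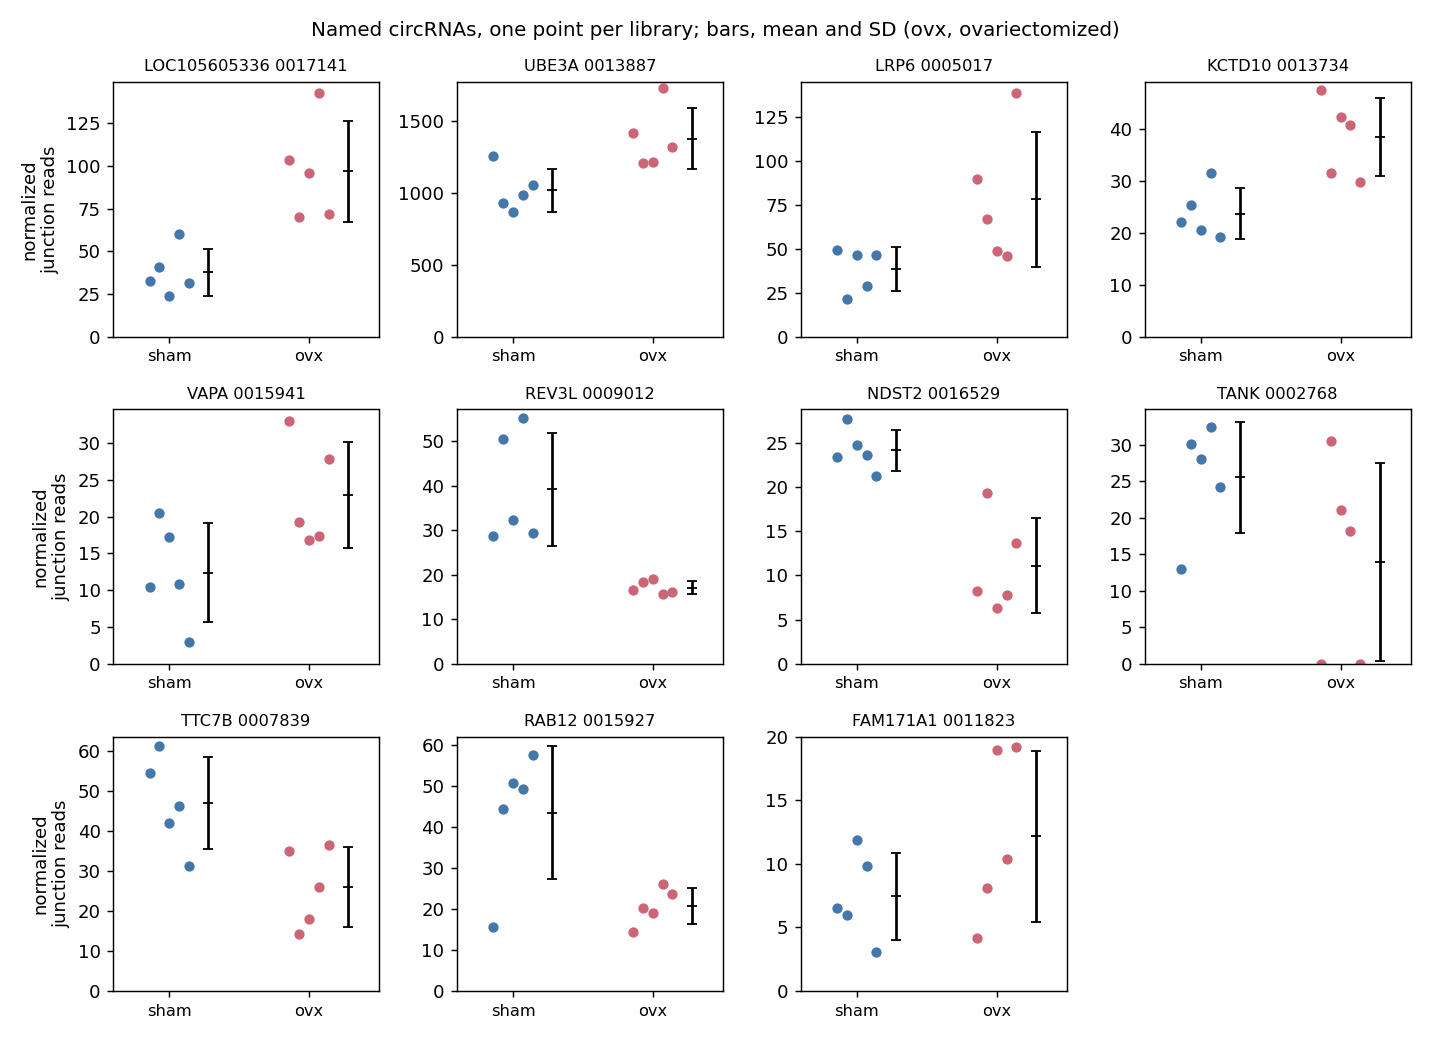
Normalized junction reads of the 10 named circRNAs and of the FAM171A1 circRNA with the most reads, one point per library, sham in blue and ovariectomized (ovx) in red, with mean and SD as bars. For LOC105605336 the ovariectomized libraries hold 70.2 to 143 normalized reads and the sham libraries 23.7 to 60.0, while for FAM171A1 the groups overlap.

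The series title names a circRNA of FAM171A1 and the kinase MAPK15. Of FAM171A1, 3 circRNAs were listed. The one with the most reads, novel_circ_0011823 (chromosome 13, 29185543 to 29191802, minus strand, exonic), was in all 10 libraries. It had 5, 5, 11, 10 and 3 junction reads in sham replicates 1 to 5 and 4, 8, 18, 12 and 31 in the ovariectomized ones. Normalized reads were 7.45 ± 3.45 in sham and 12.2 ± 6.71 in ovariectomized libraries (SD, n = 5 each), which did not differ beyond the spread (exact permutation p = 0.214). It was below the filter of the limma fit. The second, novel_circ_0011821 (29166693 to 29191802), had 3 reads in sham replicate 5, and 2 and 10 in ovariectomized replicates 4 and 5. The third, novel_circ_0011822 (29171429 to 29191802), had 5 and 3 reads in sham replicates 3 and 4. The estrogen receptor gene ESR1 had 1 listed circRNA, novel_circ_0009386, with 5 reads in ovariectomized replicate 2. MAPK15, ESR2 and GPER1 had no listed circRNA.

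With reads summed per host gene, no host passed the threshold among 753 tested by limma, with 45 at an unadjusted p under 0.05, and no gene list changed. Only the list of transcripts abundant in adult muscle fibers had enough tested hosts for a test. Of its 11 tested hosts, 3 had a higher and 8 a lower estimate after ovariectomy, with a median log2 fold change of -0.37. The median was -0.24 with library totals alone, -0.21 without ovariectomized replicate 1 and -0.16 without ovariectomized replicate 5. Camera gave an adjusted p of 0.0959 in limma, and p = 0.119 with an estimated correlation. Its 2 hosts with the smallest p were TTN, at -0.42 ± 0.19 on the log2 scale, and JPH1, which encodes a junctophilin of the triad membranes, at -0.81 ± 0.39. Both had a limma adjusted p of 0.759, and adjusted over the list alone 0 of 11 passed. Within the TTN sum, novel_circ_0002388 held 8114 of 12696 reads and was at -0.10 ± 0.23 (SE).

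The other lists had at most 4 tested hosts, and 12 had none. In the MAPK list, 13 of 41 genes hosted a circRNA and 4 were tested, with log2 fold changes of -0.80 ± 0.32 for MAP2K4 and -0.17 ± 0.26 for MAPK8. In the list of muscle regulators and satellite cells, 3 hosts were tested. MET, which encodes the receptor of hepatocyte growth factor, had 69.6 ± 19.2 normalized reads in sham and 110.9 ± 27.0 in ovariectomized libraries (SD, n = 5 each). It was the 1 host of these 3 that passed when adjusted over the list alone, with a limma adjusted p of 0.713 over all hosts, and its ovariectomized replicate 5 had 63.6. MEF2C, a muscle transcription factor gene, was at -0.87 ± 0.52, at -0.25 without ovariectomized replicate 5 and at -1.32 without ovariectomized replicate 1. In the growth list, 17 of 31 genes hosted a circRNA, and IGF1R was at -0.45 ± 0.26 among 4 tested. Of the fiber type lists, MYH2 was at -0.67 ± 1.32 and ATP2A1 at -0.36 ± 0.58 for fast fibers, and MYOZ2 at 0.11 ± 0.63 for slow fibers. The mean normalized reads of MYH2 went the other way, 40.5 ± 24.8 in sham and 43.9 ± 38.7 in ovariectomized libraries (SD, n = 5 each), and its log2 fold change was 0.52 without ovariectomized replicate 2. In the list of glycolysis and glycogen, GYS1, a glycogen synthase gene, was at 0.51 ± 0.30. All 4 tested fatty acid oxidation genes had negative ones, with ACADL at -0.37 ± 0.32 and HADHA at -1.07 ± 1.09, which rests on ovariectomized replicate 1 with no entry. In the degradation list NEDD4 was at -0.52 ± 0.42 and CAST at -0.19 ± 0.36. Among genes of other cell types, COL14A1 was at -1.11 ± 0.72, COL15A1 at 0.46 ± 0.38, FLT1 at -0.62 ± 0.46 and ABCC9 at 0.14 ± 0.25. FDFT1, of the cholesterol list, was at -0.06 ± 0.50. Of the 20 hosts named from the lists, 16 moved by over 1.5 times and 6 changed sign when some library was left out. Outside MET, 0 of these hosts passed when adjusted over the list alone. The estrogen target list had 6 of 25 genes with a circRNA, together 107 reads, and none tested.

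**Figure D3:**
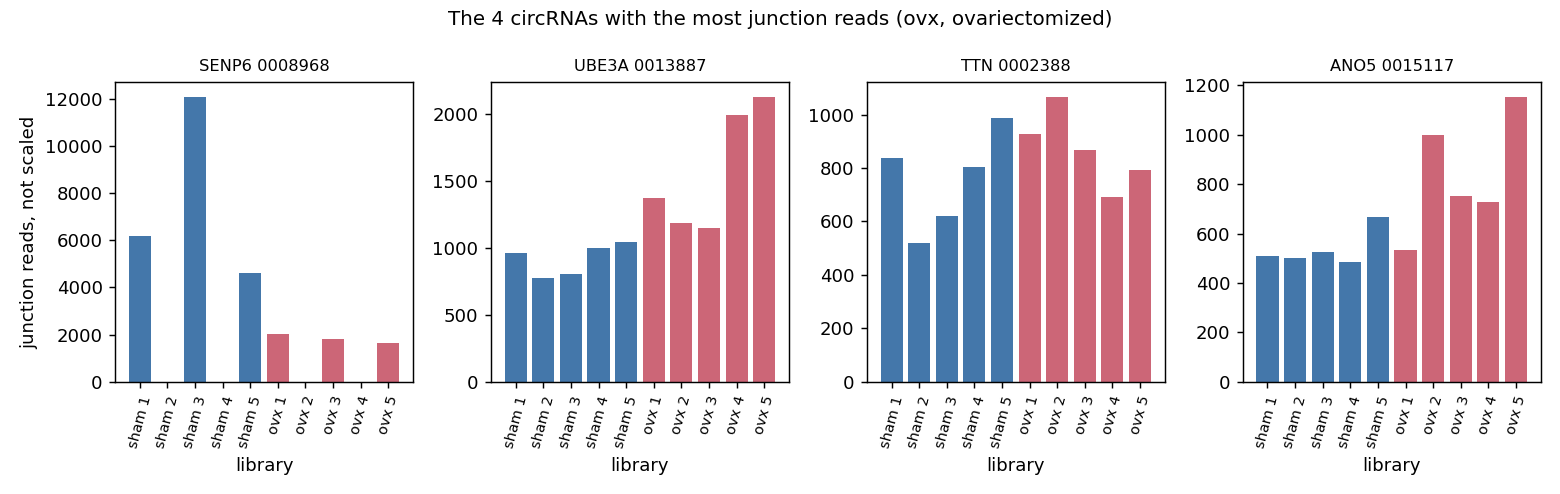
Junction reads, not scaled, of the 4 circRNAs with the most reads in each library, sham in blue and ovariectomized (ovx) in red. The SENP6 circRNA has 1659 to 12107 reads in 6 libraries and no entry in the other 4, while those of UBE3A, TTN and ANO5 are in all 10.

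The most abundant circRNA differed between libraries within each group. It was novel_circ_0008968 of SENP6 (chromosome 8, 2532167 to 2535307, plus strand, exonic), with 6172, 12107 and 4592 reads in sham replicates 1, 3 and 5 and 2001, 1800 and 1659 in ovariectomized replicates 1, 3 and 5. It had no entry in replicates 2 and 4 of either group. Over all 10 libraries, those without an entry included, the exact permutation p of its normalized reads was 0.175. Their means were 5143.5 ± 5568 in sham and 999 ± 994 in ovariectomized libraries (SD, n = 5 each). With the replicate number as a block, limma called it lower after ovariectomy, but whether the numbers pair the samples is not settled.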

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

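Of 76 groups of values tested for a sample far from the others, 8 stood out. Chance alone flags about 1 in 20 where values are normally spread. For sparse counts this rate does not hold, as a circRNA listed in 1 library of a group stands out by construction. The tests of the SENP6 circRNA, of the LOC105605336 circRNA and of the direction of change, and the splits of the libraries, were chosen after the results were seen. In each count of splits below, the real grouping is itself among the splits counted.

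Ovariectomized replicate 5 had 67061 junction reads where the others of its group had 39045 to 46968. Sham replicate 1 listed 2559 circRNAs where the others listed 3273 to 3483. The ESR1 circRNA novel_circ_0009386 had 5.09 normalized reads in ovariectomized replicate 2 and no entry in the others. The FAM171A1 circRNA novel_circ_0011821 had 3.03 normalized reads in sham replicate 5, alone in its group, and 6.20 in ovariectomized replicate 5, where the others had at most 1.73. Summed over its circRNAs, MET had 63.6 normalized reads in ovariectomized replicate 5 against 116.5 to 128.4 in the others. ATP2A1 had 2.68 in sham replicate 1 against 12.7 to 15.1. HADHA had 0 in ovariectomized replicate 1 against 42.8 to 56.6.

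The SENP6 circRNA novel_circ_0008968 took 2.47% to 24.3% of the reads of 6 libraries, replicates 1, 3 and 5 of each group, and had no entry in the other 4. An absence of SENP6 RNA is argued against by novel_circ_0008942 of the same gene, listed in 10 of 10 libraries with 34 to 180 reads. In sham it had 34 and 57 reads in replicates 2 and 4, against 105, 104 and 111 in replicates 1, 3 and 5. In the ovariectomized group it had 76 and 113, against 50, 73 and 180. A lower level of SENP6 RNA in some libraries stays open, since reads of a circRNA do not measure the host RNA. A library batch that acts on many circRNAs is argued against by the count of circRNAs of other genes in exactly the same 6 libraries, which was 2, the median over the other sets of 6 libraries, whose 95th percentile was 4.6. Ovariectomy does not account for its presence, since 3 of 5 libraries in either group list it. A variant of the gene in some animals may account for it and stays open. An example is a duplicated exon that would give the same junction in linear RNA. The 0.611 to 0.823 non-junction reads per junction read of novel_circ_0008968, against a median of 6.90 over tested circRNAs, do not decide this. The pattern is not in this circRNA alone: novel_circ_0008966 of SENP6, with the same start, was listed in the same 6 libraries only. It had 39, 130 and 70 reads in sham and 15, 16 and 9 in ovariectomized replicates 1, 3 and 5. A batch by replicate number that acts on these 2 circRNAs was not tested.

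More circRNAs were lower than higher after ovariectomy at an unadjusted p under 0.05, 33 against 9. Scaling between libraries may account for the split: with library totals alone 69.2% of such circRNAs were higher, against 21.4% in the main scaling. Another scaling moves all circRNAs of a library together, so this shows that the split depends on scaling, not which scaling is right. Scaling is not shown to be the whole source: limma trend on the authors' normalized values, which changes scaling, transform and variance model together, gave 21 higher and 21 lower, or 21 and 20, with pseudocounts of 1 and 0.1, while median-of-ratios factors in voom gave 9 and 25. Without ovariectomized replicate 5 the split also turned, to 24 higher and 11 lower. The number itself cannot be told from chance, since 20 of 100 drawn splits of the libraries gave as many as the real 42, and the highest of the other splits gave 60.

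The LOC105605336 circRNA novel_circ_0017141 had more reads in each ovariectomized than in each sham library, without passing the threshold. The level of the host RNA stays open: the log2 ratio of mean non-junction reads was 0.17, and junction reads per non-junction read were 2.46 ± 0.837 in sham and 6.01 ± 2.49 in ovariectomized libraries (SD, n = 5 each, exact permutation p = 0.0159). The limma adjusted p of that ratio was 0.448 over 735 circRNAs, this one was picked for its junction reads, and the sources used do not define non-junction reads. A shift of the ratio common to all circRNAs of a library was not removed either. Log2 fold changes were at least 1.20 with any one library left out, so the estimate rests on no single library. As all ovariectomized libraries lay above all sham libraries, leaving out 1 could not bring the change to 0. This is therefore no test of that explanation. The change was 1.38 or more under both other scalings, so it does not depend on the choice among the scalings run. An effect of ovariectomy on this circRNA is a hypothesis that stays open, and the circRNA was picked from 738 for its p. Its limma adjusted p was 0.208 in the main fit and up to 0.717 without sham replicate 3. That p was 7.57e-05 with no filter beyond 1 read and 0.00259 with at least 5 libraries at 2 or more reads. With the replicate number as a block it was 0.0109. Under the filter of at least 5 libraries, 74 of the splits besides the real grouping also gave a call. No count of splits is given for the setting with no filter.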

How the results depend on the processing

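The counts of circRNAs at an unadjusted p, the removal of the SENP6 circRNA, the count of circRNAs in one group only and the splits of the libraries were chosen after the data were seen. The planned edgeR and DESeq2 fits were set up for plain count columns and were not run. The lists were unpacked to whole counts, on which a count model could be run. The count of changed circRNAs was 0 in limma voom, under median-of-ratios factors, library totals, quality weights, no robust variances, limma trend with pseudocounts of 1 and 0.1, host sums, an adjusted p under 0.10, and without each library. It was 30 with no filter beyond 1 count and 4 with at least 5 libraries at 2 or more reads, a looser filter at this depth. Those 4 were the circRNAs of PCNT, TANK, UBE3A and LOC105605336, and 29 of 100 splits gave as many, with 13 the highest. Under this filter 74 of the splits besides the real grouping gave a call. In the main fit a count of 0 is reached by all 100 splits by construction, so they do not test it. The highest of the others there gave 1. At an unadjusted p under 0.05 these filters gave 540 and 213 circRNAs, and leaving out each library gave 31 to 55. More circRNAs were tested under both filters.

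With the replicate number as a block the count was 3, 2 circRNAs of SENP6 and that of LOC105605336, whose adjusted p was 0.0109. Any 2 libraries correlated at 0.42 to 0.65. The check of pairing used another correlation, which was 0.05, 0.19, 0.05, 0.11 and -0.12 for same-numbered samples. By it, only replicate 2 correlated best with its own number. These values do not show that the numbers pair the samples. They cannot exclude it either, as both of these SENP6 circRNAs follow the replicate number in either group. Under the block the TANK circRNA was at -0.59 and that of VAPA at 0.63, MYH2 was at 0.15 and HADHA at 0.010, the median of the muscle fiber list was -0.21, and the ratio of the SRSF1 circRNA had an adjusted p of 0.0688, with 0 past the threshold. With library totals alone FDFT1 was at 0.12. The cause was not tested.

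The number of changed gene lists was 0 in every setting run, which all 100 splits likewise reach, with 1 the highest. The 10 named circRNAs that missed the threshold kept their direction in every setting run. The FAM171A1 circRNA kept its direction in all settings run, from 0.49 to 0.95 on the log2 scale without each library. Without each library, the difference in junction reads ran from -18.25 (without ovariectomized replicate 5) to 6986. That in circRNAs listed ran from -154.8 (without sham replicate 1) to 76.2. Without the SENP6 circRNA, the difference in the share of the 10 most abundant circRNAs was 1.01 and in the exonic share 0.0487. With that circRNA kept, these differences ran from -8.47 and -0.601 without sham replicate 4 to -3.00 and -0.0080 without sham replicate 3. Leaving out each library gave log2 fold changes of -0.28 to 0.038 for MAPK8, -0.26 to 0.54 for MYOZ2, -1.46 to 0.52 for MYH2, -0.35 to 0.13 for CAST, -1.55 to 0.10 for HADHA and -0.27 to 0.27 for FDFT1. It gave 7 to 14 circRNAs in one group only, since 4 libraries then suffice.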

Other observations

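All of the following were looked at after the data were seen. Some circRNAs were listed in all 5 libraries of one group and none of the other. Those of PCNT (novel_circ_0001213, 3 to 11 reads), HELZ (novel_circ_0011135, 2 to 10), XPR1 (novel_circ_0011503, 2 to 6) and ATP8B1 (novel_circ_0016040, 2 to 12) were listed in sham, and that of MITD1 (novel_circ_0004093, 3 to 12) in ovariectomized libraries. Chance cannot be excluded, since 31 of all 126 splits gave at least these 5, and the highest of the others gave 11. Of the 738 tested circRNAs, 10 had groups that do not overlap, where chance gives 0.794%, and 11 of 100 splits gave as many, the highest of the others 12.

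Junction reads were also compared with the non-junction reads at the same ends, over 735 circRNAs. The sources used do not define the non-junction reads, which were taken as reads at the ends of a circRNA that do not cross its junction. In 1 the ratio differed past the threshold by limma. It was novel_circ_0011146 of SRSF1, a splicing factor gene (chromosome 11, 8494451 to 8495842), with an adjusted p of 0.00753. Sham replicates 1 to 5 held 3, 7, 6, 4 and 4 junction reads beside 921, 1158, 902, 734 and 1254 non-junction reads. The ovariectomized ones held 23, 14, 15, 21 and 33 beside 847, 777, 590, 803 and 582. The log2 ratio was higher by 2.48 ± 0.41 (SE), and by 2.23 to 2.64 without each library. With the replicate number as a block it was again higher by 2.48, but the limma adjusted p was 0.0688, not past the threshold. The number of circRNAs past the threshold was 2 without sham replicate 5 or without ovariectomized replicate 1. Of 100 splits, 2 gave as many such circRNAs, the real one and 1 other, and the highest of the others gave 1. In the limma voom fit of its junction reads alone, the log2 fold change was 1.77 ± 0.85 with an adjusted p of 0.781. At an unadjusted p under 0.05 the limma ratio fit gave 57 circRNAs, against 36.75 expected by chance. Those with the smallest p were higher after ovariectomy. The fit did not remove a shift common to all circRNAs of a library, so a change particular to the SRSF1 circRNA is not shown. That ovariectomy may raise the SRSF1 circRNA relative to its host RNA is a hypothesis, as the ratio was among several measures tried.

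A share of reads at circRNA ends that cross the junction was also taken, on the same reading. Each junction read was counted at both ends of its circRNA. Non-junction reads were summed over all circRNAs, so those at an end shared by several circRNAs may be counted more than once. The share is therefore not a plain share of reads. It was 3.04% ± 0.576 in sham and 3.85% ± 0.613 in ovariectomized libraries (SD, n = 5 each, exact permutation p = 0.0635). With the SENP6 circRNA included, leaving out each library gave differences of 0.580 to 1.02 percentage points, the highest without sham replicate 3 (exact p = 0.0317). Without the SENP6 circRNA, and with all 10 libraries, the difference was 1.05 (exact permutation p = 0.00794, the smallest possible). This measure was outside the planned family and its p is not adjusted.

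Among host sums, FKBP5, which encodes a co-chaperone of steroid receptors, had the second smallest p. It had 41.9 ± 13.2 normalized reads in sham and 16.2 ± 13.0 in ovariectomized libraries (SD, n = 5 each), with a limma adjusted p of 0.697. The LOC105605336 sum had an adjusted p of 0.0762. RC3H2 had another circRNA, novel_circ_0004316, that was present in some libraries, with 307, 214, 237 and 31 reads in sham replicates 1, 3, 4 and 5, 262 and 436 in ovariectomized replicates 1 and 5, and no entry in the others.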
